A study of Arabidopsis thaliana with 36 samples.

How the data were processed

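RNA abundance was measured in roots of Arabidopsis thaliana, accession Columbia, on 36 single-colour Affymetrix arrays, 1 per RNA sample. Each plant had a pair of main roots in separate compartments of a plate. The labels of all samples give a pretreatment with 0.5 mM ammonium succinate, 0.3 mM sucrose and a plant age of 12 to 14 days. On uniform plates (C) both compartments held the same salt, 5 mM KNO3 or 5 mM KCl. On split plates (Sp) one side held KNO3 and the other KCl, and the roots of each side were sampled apart. Roots were taken 2 hours, 8 hours or 2 days into the treatment, which gives 12 groups (C.NO3, Sp.NO3, C.KCl and Sp.KCl at each time) of 3 biological repeats.

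The deposited intensity values are MAS5 signals on a linear scale, which the authors had scaled so that the mean of each array, trimmed by 2% at either end, comes to 500. MAS5 is named in the submitters' processing notes without a version. The scaling was read from the values, and all other upstream steps are not given in the sources used here. No detection calls and no scanner files were among the files. The median signal of an array lay between 194 and 222 and the highest between 17590 and 31289. The number of arrays, 3 per group, limits the precision.

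For the KCl samples the titles and the treatment characteristics contradict each other: samples titled as uniform carry the split treatment in their characteristics, and the reverse. The titles were followed, since the source names of the samples repeat them. An exchange of the C.KCl and Sp.KCl groups was among the alternatives, and every comparison that uses KCl arrays rests on this reading.

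Of 22810 probe sets, 64 control probe sets were left out. Signals were converted to log2 after adding 16 and were not normalized further. Probe sets with a mean below the 30th percentile, which corresponds to a signal of 68.9, were left out, and 15922 were tested. In R 4.3.3, limma 3.58.1 fitted the mean of each of the 12 groups to all 36 arrays with lmFit, took contrasts with contrasts.fit and moderated the variances with eBayes and an intensity trend. The fit had 24 residual degrees of freedom and a median of 7.09 from the prior. The p-values were two-sided and were adjusted by the Benjamini-Hochberg method over the 15922 probe sets within each contrast, and the threshold was 0.05. Differences are given on the log2 scale with the standard error (SE) of the fit.

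The contrasts were nitrate against chloride on uniform plates and on split plates, and split against uniform plates on the nitrate side and on the chloride side. Each was taken as the mean over the 3 times (9 arrays per side) and at each time (3 per side). Interactions of medium with plate, medium with time and plate with time, and the effect of time, were tested in the same fit. On split plates both salts were offered to each plant, which pairs the sides. The titles give a repeat number without tying it to plants. Same-numbered arrays were compared by the correlation of their deviations from the group means. They were treated as paired where every same-numbered pair of a comparison exceeded 0.1. Over the times this held for uniform plates, at 2 hours for all 4 comparisons, at 8 hours for all but the nitrate side, and at 2 days for uniform plates. There the value with the replicate number within time as a block stands beside a count where it differed by more than 1.5 times, and beside a gene where it changed the call. It is called the blocked value, and is also given where it changed a count or a call in the other comparisons. Adjusted p-values of genes that kept their call also differed between the fits, and most of these blocked values are not given.

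Genes were named from the platform's annotation table, which gives 1 gene for 13513 probe sets, several for 503 and none for 8794. Of the probe sets tested, 8792 had 1 gene, 326 several and 6804 none. RefSeq locus tags (assembly TAIR10.1) were found for 13436 probe sets with 1 gene. Probe sets without a listed gene were counted and not named. The table lists none of the 12 nitrate-related genes that were to be named whatever their p-value, so that no value is given for them. The genes named are, for each comparison over the times, the 5 higher and 5 lower of largest difference past the threshold with 1 sign at every time, then up to 4 members past the threshold and up to 2 others from each gene list. At each time they are the 3 higher and 3 lower of largest difference, and for interactions and time the 5 of smallest p. Genes outside this rule are marked where they appear.

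Gene lists were fixed beforehand: 25 lists with 278 members, of which 38 had a probe set naming them alone and 22 were tested. These 22 fall into 11 lists: nitrate reduction and reductant supply (2 of 11 members tested), regulators of the nitrate response (3 of 21), type-A cytokinin response regulators (2 of 10), CC-type glutaredoxins (3 of 13), auxin response and transport (2 of 16), cell division (2 of 17), potassium and chloride transport (2 of 9), sulfate uptake and assimilation (1 of 11), the circadian clock (1 of 14), and markers of photosynthetic shoot tissue (2 of 19) and of root hairs (2 of 7). A result for a list covers its tested members only. The other 14 lists had no tested member and gave no result. Lists with 3 or more tested members were tested with camera at its preset correlation of 0.01 and again with an estimated correlation. Probe sets called higher or lower on uniform plates at 2 hours were followed as sets in the later split against uniform contrasts. Gene families and plastid-encoded genes were tested in the same way, but were chosen after the data were seen.

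RNA and labelling quality was followed with a 3′–5′ index, the mean log2 difference between the 3′ and 5′ control probe sets of actin, GAPDH and ubiquitin. The alternatives were quantile normalization, no filter and a filter at the 50th percentile, pseudocounts of 1 and 64, no variance trend, the replicate number as a block of 3 or of 9 levels, exchanged KCl groups, a fit to the compared arrays only, and each array left out in turn. A further alternative, called the methods' test, follows the design text: a linear model with medium, plate and time and their interactions, p below 0.001 and q below 0.2, then Tukey's test at 0.05. All of these, like the lists and contrasts, were planned before the data were examined. A fit with the 3′–5′ index as a covariate and means without the arrays of 2 hours were added afterwards. The procedure was tested on simulated data with 200 changed probe sets. A log2 change of 1 was recovered in 99% of them for uniform plates over the times and in 89% at 2 hours. A change of 0.5 was recovered in 82% and 29.5%. For these comparisons the share of false calls was 2.38% and 3.28% at 0.5, and 4.35% and 4.3% at 1. At a change of 2 it was 7.41% and 8.68%, above the threshold of 0.05. On the chloride side at 2 days it was 8.47% at 0.5 and 9.63% at 2, also above 0.05, and 4.21% at 1.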

Results

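The data are signals of 22810 probe sets in 36 root samples of Arabidopsis, 3 from each of 12 groups. The groups combine the plate (uniform, C, or split, Sp), the salt around the sampled roots (KNO3 or KCl) and the time after transfer (2 hours, 8 hours or 2 days). The comparisons ask how roots respond to nitrate in their own compartment, and whether that response depends on what the other compartment of the same plant holds. Median signals of the arrays lay between 194 and 222, and arrays of a group correlated with each other at 0.961 to 0.987. The 3′–5′ index of RNA and labelling quality averaged 0.755 ± 0.145 (SD, n = 3) in C.KCl at 2 hours against 0.381 ± 0.150, 0.501 ± 0.0282 and 0.454 ± 0.137 in C.NO3, Sp.NO3 and Sp.KCl at that time. Which KCl arrays are uniform and which are split was taken from the titles, which the characteristics contradict.

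Where both compartments held the same salt, genes were higher or lower on nitrate over the times. AT4G39675 was higher on nitrate than on chloride by a log2 of 2.49 ± 0.25 (SE, n = 9 per salt, adjusted p = 4.39e-08), and at 2 hours by 1.48 ± 0.44 (adjusted p = 0.0673, blocked 0.0287). AT1G49500 was 3.68-fold higher (1.88 ± 0.16), AT5G01740 3.08-fold (1.62 ± 0.12) and AT5G10210 2.89-fold (1.53 ± 0.14). Lower on nitrate were OCT1, an organic cation and carnitine transporter (log2 -1.46 ± 0.17), AT4G32950, a protein phosphatase of the PP2C family (-1.43 ± 0.07, adjusted p = 3.47e-15), AT4G01390, a protein with a TRAF-like domain (-1.42 ± 0.14), and AT5G04120, of the phosphoglycerate mutase family (-1.36 ± 0.28). Over the 3 times, 541 probe sets passed the threshold, 255 higher and 286 lower on nitrate, 1371 (649 higher and 722 lower) in the blocked fit, and 873 by the methods' test. Of the 14 named genes past the threshold, 13 had all 9 nitrate arrays on the called side of the chloride mean of their time. AT4G32950 had 8 of 9.

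Of the 21 listed regulators of the nitrate response 3 were tested, and all 3 rose on uniform plates. They are AT3G25790 (HHO1), AT1G25550 (HHO3) and AT1G68670 (HHO2), MYB-like transcriptional repressors of nitrate and phosphate starvation genes, with log2 differences of 0.79 ± 0.10, 0.65 ± 0.09 and 0.52 ± 0.08. The count was 3 of 3 adjusted over the list alone as well, and these 3 rose as a set (adjusted p = 3.58e-10, and adjusted p = 2.30e-06 with an estimated correlation). In the list of potassium and chloride transport, AT3G45700 (NPF2.4), a chloride transporter of xylem loading, was higher by 0.35 ± 0.08 (adjusted p = 0.0101), and AT3G45710 (NPF2.5) differed by 0.09 ± 0.07 (adjusted p = 0.584). Adjusted over the list alone the count was also 1 of 2. With exchanged KCl groups the call of NPF2.4 was lost (adjusted p = 0.518).

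No tested member of the other 9 tested lists passed the threshold over all probe sets on uniform plates. With 1 to 3 members tested per list, this does not speak for the lists as wholes. The 6-phosphogluconate dehydrogenases AT1G64190 (PGD1) and AT5G41670 (PGD3), in the list of nitrate reduction and reductant supply, differed by 0.16 ± 0.06 and -0.05 ± 0.08. PGD1 passed in the blocked fit (adjusted p = 0.0405 against 0.120) and adjusted over the list alone. GI, of the circadian clock, differed by -0.25 ± 0.10 (adjusted p = 0.168, blocked 0.0334) and passed adjusted over the list alone, which it makes up by itself. Among the CC-type glutaredoxins, AT3G62930 (GRXS6) differed by 0.30 ± 0.13, AT2G47880 by 0.09 ± 0.17 and AT1G06830 by -0.59 ± 0.23 (adjusted p = 0.163, blocked 0.0485). Adjusted over the list alone 1 was higher and 1 lower, the list had a median of 0.09, a mean of -0.06 and an upward camera statistic, and its adjusted p was 0.880 with the preset and with the estimated correlation.

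The tested members of the remaining lists gave no call on uniform plates, either over all probe sets or adjusted over the list alone. The type-A cytokinin response regulators ARR15 and RR16 differed by 0.10 ± 0.13 and -0.16 ± 0.14, and the auxin genes WES1 and LBD16 by -0.05 ± 0.08 and 0.22 ± 0.13. PRL and AUR1, of cell division, differed by -0.11 ± 0.11 and 0.08 ± 0.07, and SIR, the sulfite reductase of sulfate assimilation, by 0.15 ± 0.07. The shoot markers RCA and LHCB4.2 differed by 0.27 ± 0.16 and 0.46 ± 0.30. RCA passed in the blocked fit (adjusted p = 0.0488 against 0.401). The root hair expansins EXPA7 and EXPA18 differed by -0.01 ± 0.07 and -0.12 ± 0.09.

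The genes that differed most on uniform plates were not the same at each time. At 2 hours the largest named increases were those of AT5G10210 (log2 1.69 ± 0.25, n = 3 per salt, adjusted p = 0.000200), AT5G62720, a membrane protein of the HPP family (1.61 ± 0.15), and AT1G49500 (1.39 ± 0.28). The largest decreases were those of AT3G28550, extensin-like (-1.82 ± 0.50, adjusted p = 0.0494), the plastid ribosomal protein gene rpl16 (-1.46 ± 0.16) and the formin AT5G07740 (-1.43 ± 0.37, adjusted p = 0.0367). rpl16 had a signal of 5311 ± 549 (SD) in C.KCl at 2 hours against 1976 ± 634 in C.NO3, 1789 ± 87.8 in Sp.NO3 and 1544 ± 95.3 in Sp.KCl. The count at 2 hours was 325 (161 higher and 164 lower), and 1176 in the blocked fit. It was 11 with the 3′–5′ index as a covariate, an alternative added after the data were seen, and all 11 were among the 325. With only the 6 arrays compared in the fit it was 8. It was 711 without C.NO3 replicate 3, 53, 178, 197, 64 and 184 without C.NO3 replicates 1 and 2 and C.KCl replicates 1, 2 and 3, and 26 with exchanged KCl groups, where rpl16 differed by 0.31 and AT3G28550, AT5G07740 and AT1G49500 lost their calls. AT3G28550 lost its call without C.NO3 replicate 1 or any C.KCl replicate (adjusted p between 0.0684 and 0.349), and AT5G07740 without C.NO3 replicates 1 and 2 or C.KCl replicates 1 and 2 (0.0600 to 0.176).

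At 8 hours AT4G39675 (log2 2.01 ± 0.44, n = 3 per salt), AT1G49500 (2.00 ± 0.28) and AT5G10210 (1.91 ± 0.25) were higher on nitrate on uniform plates. OCT1 (-1.67 ± 0.30), AT4G32950 (-1.47 ± 0.12, adjusted p = 2.92e-09) and GH9C3, a glycosyl hydrolase (-0.85 ± 0.20, adjusted p = 0.0429), were lower. The count was 62 (41 higher and 21 lower), 296 in the blocked fit, and 33, 36, 33 and 38 without C.NO3 replicates 1 and 3 and C.KCl replicates 1 and 3. AT4G39675 and GH9C3 lost their calls without any 1 of the 6 arrays (adjusted p from 0.0550 to 0.187 and from 0.0679 to 0.270), and OCT1 without C.NO3 replicate 1 (0.0531). With exchanged KCl groups GH9C3 was no longer called (0.732).

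After 2 days 103 of the called probe sets on uniform plates differed by a log2 of 1 or more, against 26 at 2 hours and 27 at 8 hours. AT5G01740 was 6.14-fold higher on nitrate (log2 2.62 ± 0.20, n = 3 per salt). AT4G39675 was higher by a log2 of 3.96 ± 0.44 (adjusted p = 3.72e-07), with a signal of 439 ± 212 (SD) on nitrate and 13.3 ± 14.2 on chloride. The latter is below the 16 added to signals, which sets the size of that difference. AT4G33720, of the family of pathogenesis-related protein 1, was 43.5-fold lower (-5.44 ± 0.72, adjusted p = 8.70e-06), with a signal of 108 ± 78.5 (SD) on nitrate and 5751 ± 3450 on chloride. AT4G01390 was 9.02-fold lower (-3.17 ± 0.23). AT3G28510, an AAA-type ATPase, was lower by a log2 of -2.65 ± 0.32, with a signal on nitrate, 12.7 ± 2.72, that is likewise below 16. AT1G73120, 6.91-fold higher (2.79 ± 0.73, adjusted p = 0.0300), lost its call without any of 5 of the 6 arrays, all but C.KCl replicate 3 (adjusted p from 0.0711 to 0.192). The count was 402 (209 higher and 193 lower), 887 in the blocked fit, and 261, 261 and 245 without C.NO3 replicates 1 and 2 and C.KCl replicate 1. It was 61 with exchanged KCl groups, where AT3G28510 and AT1G73120 lost their calls (adjusted p = 0.226 and 0.926).

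**Figure D1:**
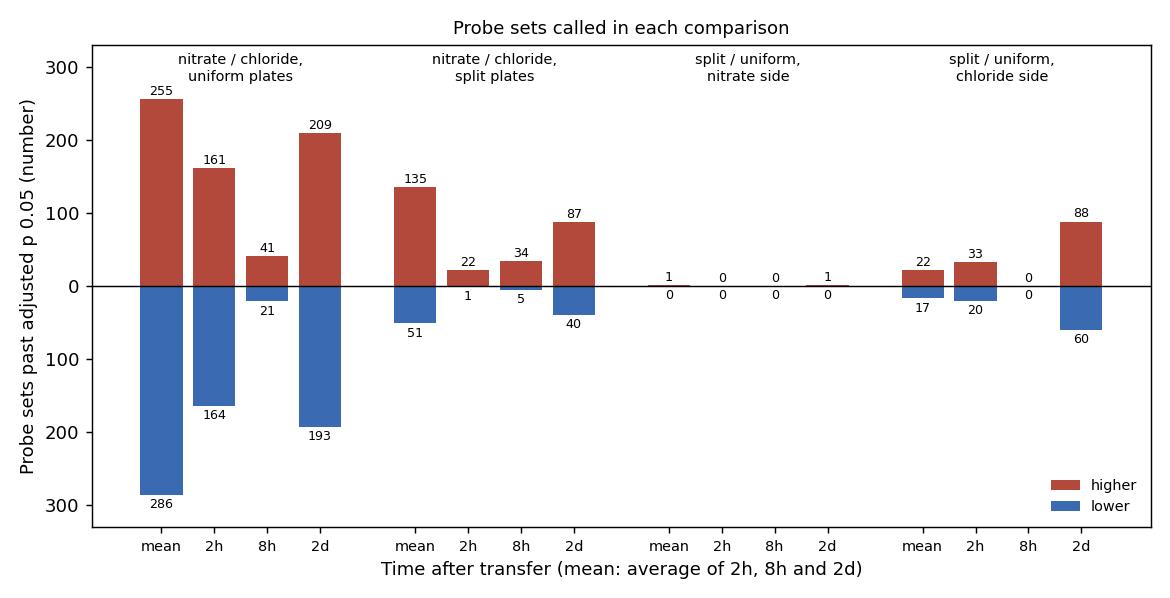
Number of probe sets past an adjusted p of 0.05 (vertical axis; higher above 0, lower below) in each of the 4 comparisons, as the mean over times and at each time (horizontal axis). Nitrate against chloride on uniform plates gave 541 over the times, and split against uniform plates on the nitrate side gave 1.

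On split plates, where both salts were offered to each plant, the roots in nitrate differed from those in chloride. AT4G39675 was 3.51-fold higher on the nitrate side (log2 1.81 ± 0.25, n = 9 per salt, adjusted p = 1.79e-05), AT5G10210 3.19-fold (1.67 ± 0.14), AT5G01740 2.74-fold (1.46 ± 0.12), AT5G62720 2.62-fold (1.39 ± 0.09, adjusted p = 1.18e-12) and AT1G49500 2.21-fold (1.15 ± 0.16). Lower on the nitrate side were AT5G04120 (-1.18 ± 0.28), OCT1 (-1.14 ± 0.17), AT4G32950 (-0.97 ± 0.07), AT1G64590 (-0.79 ± 0.11) and AT1G22160 (-0.72 ± 0.14). Over the times 186 probe sets passed, 135 higher and 51 lower, 372 in the blocked fit, and 389 by the methods' test. Of the 16 named genes past the threshold 14 had all 9 nitrate arrays on the called side of the chloride mean, and AT5G04120 and SIR had 8. AT5G04120 had an adjusted p of 0.0237 (blocked 4.16e-05). In the fit without a block its call was lost without any of Sp.NO3 2 hours replicate 3, Sp.KCl 2 hours replicates 1 and 2, Sp.NO3 8 hours replicates 2 and 3, Sp.KCl 8 hours replicate 1, Sp.NO3 2 days replicate 2 and Sp.KCl 2 days replicates 1 and 2 (0.0501 to 0.0744).

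Among the regulators of the nitrate response on split plates, HHO1 (AT3G25790) rose by 1.05 ± 0.10 and HHO3 (AT1G25550) by 0.59 ± 0.09, and HHO2 (AT1G68670) differed by 0.27 ± 0.08 (adjusted p = 0.0924, blocked 0.00601). The count was 2 of 3, and 3 of 3 in the blocked fit and adjusted over the list alone. The 3 tested members rose as a set (adjusted p = 1.07e-12, and adjusted p = 3.11e-07 with an estimated correlation). Both 6-phosphogluconate dehydrogenases rose, PGD1 (AT1G64190) by 0.29 ± 0.06 (adjusted p = 0.00276) and PGD3 (AT5G41670) by 0.37 ± 0.08 (adjusted p = 0.00831), also adjusted over the list alone, but PGD3 lost its call with exchanged KCl groups (adjusted p = 0.656). SIR rose by 0.28 ± 0.07, at an adjusted p of 0.0489 (blocked 0.00475). In the fit without a block, leaving out any of 12 of the 18 arrays gave 0.0523 to 0.163. They were Sp.NO3 2 hours replicates 1 and 3, Sp.KCl 2 hours 2, Sp.NO3 8 hours 1 and 2, all 3 of Sp.KCl 8 hours, and replicates 1 and 2 of both groups of 2 days. It also passed adjusted over the list alone, which it makes up by itself.

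In the CC-type glutaredoxins GRXS6 (AT3G62930) was higher by 0.56 ± 0.13 on split plates (adjusted p = 0.0238, blocked 0.00601). AT2G47880 and AT1G06830 differed by 0.11 ± 0.17 and -0.01 ± 0.23. Over all probe sets and adjusted over the list alone 1 of 3 was called. The set's adjusted p of 0.0450 became an adjusted p of 0.0541 with an estimated correlation, and 0.0586 in the blocked fit. With the 12 members present before the filter on dim probe sets the set's adjusted p was 0.290. The call of GRXS6 was lost without any of 9 of the 18 arrays (adjusted p from 0.0502 to 0.0840): Sp.NO3 2 hours replicates 1 and 2, Sp.KCl 2 hours 3, replicates 1 and 3 of both groups of 8 hours, Sp.NO3 2 days 2 and Sp.KCl 2 days 3. With exchanged KCl groups GRXS6 and SIR lost their calls (both 0.115) and HHO2 gained one (0.00158). ARR15, RR16, WES1, LBD16, PRL, AUR1, AT3G45700 (NPF2.4), AT3G45710 (NPF2.5), GI, RCA, LHCB4.2, EXPA7 and EXPA18 did not pass on split plates, over all probe sets or adjusted over their lists alone, with differences between -0.13 ± 0.14 (RR16) and 0.18 ± 0.13 (ARR15).

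At 2 hours on split plates AT5G10210 (log2 1.57 ± 0.25, n = 3 per salt), AT5G62720 (1.42 ± 0.15) and AT5G01740 (0.97 ± 0.20) were higher on the nitrate side. The 3 tested glutaredoxins differed by 0.54 ± 0.23 (GRXS6), 0.02 ± 0.29 (AT2G47880) and 0.39 ± 0.39 (AT1G06830), and 0 of 3 passed, over all probe sets or adjusted over the list alone. Their set had an adjusted p of 0.0224, and an adjusted p of 0.0301 with an estimated correlation. The count was 23 (22 higher and 1 lower), 42 in the blocked fit, 150 with exchanged KCl groups, and 12, 12, 14, 15 and 14 without Sp.NO3 replicates 1, 2 and 3 and Sp.KCl replicates 1 and 3. AT5G01740 lost its call without Sp.NO3 replicates 1 and 2 or Sp.KCl replicates 1 and 3 (adjusted p from 0.216 to 0.258). With only the 6 arrays compared in the fit the count was 0.

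At 8 hours AT5G10210 (log2 1.97 ± 0.25, n = 3 per salt), AT5G01740 (1.45 ± 0.20) and AT5G62720 (1.39 ± 0.15) were higher on the nitrate side of split plates. OCT1 (-1.54 ± 0.30, adjusted p = 0.00816), AT4G32950 (-1.09 ± 0.12) and AILP1, an aluminium-induced-like protein (-0.53 ± 0.10, adjusted p = 0.00562), were lower. The count was 39 (34 higher and 5 lower) and 117 in the blocked fit. OCT1 lost its call without Sp.NO3 replicate 3 (adjusted p = 0.125) or Sp.KCl replicate 1 (0.222), and AILP1 without Sp.NO3 replicate 1 (0.0535) or Sp.KCl replicate 2 (0.0654) and with exchanged KCl groups (0.145).

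After 2 days on split plates AT4G39675 was 6.49-fold higher on the nitrate side (log2 2.70 ± 0.44, n = 3 per salt), AT5G01740 3.86-fold (1.95 ± 0.20) and AT3G45160 3.61-fold (1.85 ± 0.32). AT4G32950 was lower (-1.51 ± 0.12, adjusted p = 2.88e-09), as were the 2-oxoglutarate-dependent oxygenase AT5G43450 (-1.19 ± 0.26, adjusted p = 0.0160) and the thaumatin AT1G20030 (-1.14 ± 0.24, adjusted p = 0.0123). AT4G33720 differed by -1.44 ± 0.72 here (adjusted p = 0.621). The count was 127 (87 higher and 40 lower), 305 in the blocked fit, and 81, 81 and 77 without Sp.NO3 replicates 1 and 2 and Sp.KCl replicate 1. AT5G43450 lost its call without Sp.NO3 replicate 1, Sp.KCl replicate 2 or Sp.KCl replicate 3 (adjusted p = 0.143, 0.0795 and 0.0570), and AT1G20030 without Sp.NO3 replicate 1 or Sp.KCl replicate 2 (0.179 and 0.0754).

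The responses on both kinds of plate shared more probe sets than independent calls would. Over the times 69 were higher on nitrate on both, against 2.16 expected, and 33 lower, against 0.916. 1 was lower on uniform and higher on split plates. Of the 255 higher and 286 lower on uniform plates, 205 and 214 had the same sign on split plates. Across the 15922 probe sets, which are not independent replicates, the differences correlated at r = 0.36 (rho 0.12), and at 0.222 without a filter on dim probe sets. With exchanged KCl groups the counts over the times were 135 on uniform and 462 on split plates.

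**Figure D2:**
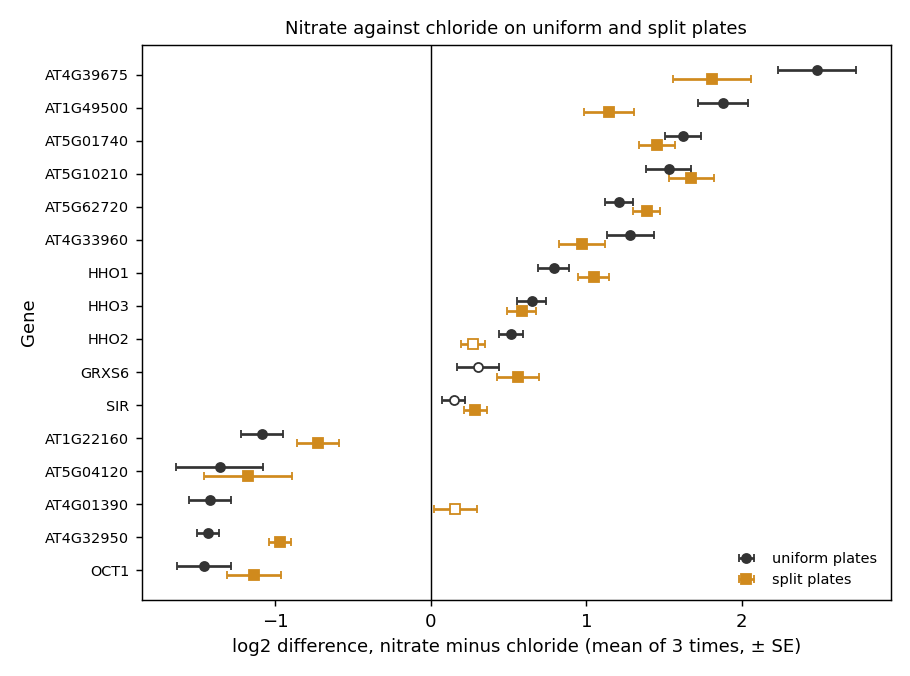
Log2 difference between nitrate and chloride (horizontal axis; mean of 3 times, bars are SE, n = 9 arrays per salt) for 16 named genes (vertical axis) on uniform plates (circles) and split plates (squares), with open symbols for an adjusted p of 0.05 or more. AT4G39675 was highest on both, at 2.49 and 1.81, and all but AT4G01390 lay on the same side of 0 on both plates.

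Nitrate-fed roots were compared between plates to ask whether chloride around the other roots of the plant changes them. The 1 probe set called over the times was that of AT4G01390. It was 1.75-fold higher on split than on uniform plates (log2 0.81 ± 0.14, n = 9 per plate, adjusted p = 0.0212, 8 of 9 arrays on that side), and at 2 days 3.44-fold (1.78 ± 0.23, n = 3 per plate, adjusted p = 0.000228), with a signal of 252 ± 52.0 (SD) against 61.7 ± 14.0. HHO2 and HHO3 differed over the times by -0.12 ± 0.08 and -0.02 ± 0.09, PGD1 and PGD3 by 0.05 ± 0.06 and 0.14 ± 0.08, and RR16 by -0.39 ± 0.14 (adjusted p = 0.924). RR16 was the member called of any list adjusted over the list alone. Limma called 1 probe set over the times, 0 at 2 hours, 0 at 8 hours and 1 at 2 days. The blocked fit called 4 over the times and 21 at 8 hours (12 higher and 9 lower). At an unadjusted p below 0.05 there were 856, 249, 1193 and 624, where chance gives 796, and the methods' test called 120, 4, 36 and 19. The call over the times was lost without any of 12 of the 18 arrays (adjusted p from 0.0542 to 0.111): C.NO3 2 hours replicates 1 and 2, Sp.NO3 2 hours 1 and 3, C.NO3 8 hours 1 and 3, Sp.NO3 8 hours 1 and 2, C.NO3 2 days 1 and 3, and Sp.NO3 2 days 1 and 2.

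Chloride-fed roots were compared between plates to ask whether nitrate around the other roots of the plant changes them. Over the times JAL33, a jacalin-like lectin, was 1.32-fold higher on split plates (log2 0.40 ± 0.07, n = 9 per plate, adjusted p = 0.0116), AT5G26260, with a TRAF-like domain, 1.24-fold (0.31 ± 0.06), and AT2G34590, a subunit of plastid pyruvate dehydrogenase, was higher by a log2 of 0.26 ± 0.06. AT4G01390 was 1.71-fold lower (-0.77 ± 0.14, adjusted p = 0.0116), AT2G28780 1.56-fold (-0.64 ± 0.13) and AT4G32950 1.27-fold (-0.34 ± 0.07). The peroxidase AT2G37130 (0.36 ± 0.08, adjusted p = 0.0496), the receptor kinase AT3G21340 (-0.55 ± 0.12, adjusted p = 0.0480) and AT5G64550 (-0.52 ± 0.12, adjusted p = 0.0477) were just past the threshold, and all of them lost the call under quantile normalization. Of the 9 named, 4 had all 9 split arrays on the called side of the uniform mean, and the fewest was 7. At single times, 7 of the 9 were called at 2 days alone, AT2G34590 at 2 hours alone and AT3G21340 at none. JAL33 differed by 0.09, 0.14 and 0.96 from the first time to the last, AT5G26260 by 0.10, 0.08 and 0.75, and AT2G34590 by 0.62, 0.05 and 0.12. HHO2 and HHO3 differed by 0.13 ± 0.08 and 0.04 ± 0.09, PGD3 by -0.28 ± 0.08 (adjusted p = 0.132, blocked 0.0118), RR16 by -0.42 ± 0.14 (adjusted p = 0.219), GRXS6 by -0.17 ± 0.13 and NPF2.5 by 0.19 ± 0.07. Adjusted over the list alone 1 reductant supply gene and 1 response regulator were lower and 1 transporter of potassium and chloride transport was higher, against 0 over all probe sets.

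The count on the chloride side over the times was 39 (22 higher and 17 lower), and 272 in the blocked fit. It was 235 without Sp.KCl 2 days replicate 3. It was 9 to 23 without any of 11 other arrays: C.KCl 2 hours replicates 1, 2 and 3, Sp.KCl 2 hours 2, C.KCl 8 hours 1 and 3, Sp.KCl 8 hours 2, C.KCl 2 days 1 and 2, and Sp.KCl 2 days 1 and 2. With the 3′–5′ index as a covariate it was 10, with only the arrays compared 12, and by the methods' test 423. JAL33, AT5G26260 and AT4G01390 stayed past the threshold in every fit with an array left out. AT4G32950, AT2G28780 and AT2G34590 fell short in 8, 10 and 11 of the 18 fits, AT2G37130 and AT3G21340 in 14 and AT5G64550 in 16 (adjusted p from 0.0510 to 0.139). All 6 did so without Sp.KCl 8 hours replicate 2, without C.KCl 2 days replicate 1 and without Sp.KCl 2 days replicate 2.

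At 2 hours on the chloride side AT3G45090 was 2.49-fold higher on split plates (log2 1.32 ± 0.29, n = 3 per plate, adjusted p = 0.0359), AT1G05270 1.94-fold (0.96 ± 0.18) and AT1G16560 1.63-fold (0.70 ± 0.10, adjusted p = 0.000437). rpl16 was 3.41-fold lower (-1.77 ± 0.16, adjusted p = 6.30e-08), LIL3:1, a light-harvesting-like protein, differed by -1.14 ± 0.19 and the kinesin AT2G28620 by -0.81 ± 0.19 (adjusted p = 0.0463). The index of quality was 0.755 in the uniform and 0.454 in the split arrays. The count was 53 (33 higher and 20 lower), 308 in the blocked fit, 6 with the index as a covariate, 80 under quantile normalization, 31 without a filter on dim probe sets, 160 by the methods' test and 1 with only the 6 arrays compared. It was 119 without Sp.KCl replicate 1, and 15, 25, 11 and 14 without C.KCl replicates 2 and 3 and Sp.KCl replicates 2 and 3. AT3G45090, AT1G05270 and AT2G28620 lost their calls without C.KCl replicate 1, Sp.KCl replicate 2 or Sp.KCl replicate 3, AT3G45090 and AT2G28620 without C.KCl replicate 3 and AT2G28620 without C.KCl replicate 2 (adjusted p from 0.0610 to 0.203).

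At 8 hours limma called 0 probe sets on the chloride side, with 327 at an unadjusted p below 0.05 and 5 by the methods' test. After 2 days AT4G39675 was higher on split plates by a log2 of 1.83 ± 0.44 (n = 3 per plate, adjusted p = 0.0293), against the C.KCl signal of 13.3 that is below 16. AT4G31330 was higher by 1.44 ± 0.35 (adjusted p = 0.0318, and 0.101 with pseudocount 64), with 2 of 3 C.KCl arrays below 16. AT2G43535, a defensin-like protein, was 2.39-fold higher (1.26 ± 0.17, adjusted p = 3.98e-05). AT4G01390 was 3.76-fold lower (-1.91 ± 0.23, adjusted p = 2.08e-05), and the oxygenase AT1G80320 and AT3G28510 were lower by log2 differences of -1.81 ± 0.35 and -1.64 ± 0.32. AT4G33720 differed by -2.20 ± 0.72 (adjusted p = 0.180). The count was 148 (88 higher and 60 lower), 404 in the blocked fit, 91 with only the 6 arrays compared, 264 without Sp.KCl replicate 3, and 70, 81, 86 and 52 without C.KCl replicates 1 and 2 and Sp.KCl replicates 1 and 2. Without Sp.KCl replicate 2 AT4G39675, AT4G31330, AT1G80320 and AT3G28510 lost their calls (adjusted p = 0.253, 0.115, 0.0904 and 0.0535). AT4G39675 and AT4G31330 also lost them without Sp.KCl replicate 1 and C.KCl replicate 2, AT4G39675 without C.KCl replicate 1 and AT4G31330 without C.KCl replicate 3 (0.106 to 0.281).

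Differences between plates on the nitrate side and on the chloride side, which share no arrays, correlated across the 15922 probe sets at r = -0.12 (rho -0.10). With exchanged KCl groups the correlation was 0.120, which is fixed, since the exchange only turns the sign of the chloride-side differences. It was -0.0566 without a filter on dim probe sets, and -0.182 to -0.0666 with an array left out. The lowest came without C.NO3 2 hours replicate 3 and the highest without replicate 1. Whether the nitrate response itself differed between plates was tested as the interaction of medium and plate, over the times. It was called for 18 probe sets, 15 with a positive and 3 with a negative difference. AT4G01390 differed by 1.58 ± 0.19 (adjusted p = 4.08e-05), AT2G28780 by 1.00 ± 0.19, rpl16 by 0.74 ± 0.13, BAT1, a brassinosteroid-related acyltransferase, by 0.54 ± 0.10 and JAL33 by -0.52 ± 0.10. The difference of rpl16 rests largely on the C.KCl arrays of 2 hours, whose 3′–5′ index averaged 0.755. Its signal there was 4909 to 5936, against 1434 to 2674 in the other groups of that time. At 8 hours all groups lay between 801 and 1353. At 2 days the signal of AT4G01390 was 61.7 ± 14.0 (SD, n = 3) in C.NO3, 252 ± 52.0 in Sp.NO3, 173 ± 49.5 in Sp.KCl and 698 ± 224 in C.KCl. With exchanged KCl groups the count was 0. No list member passed over all probe sets, and adjusted over the list alone 1 gene of reductant supply was higher.

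The interaction count was 30 without C.NO3 2 hours replicate 3 and 70 without Sp.KCl 2 days replicate 3, and 6 to 11 without any of 17 other arrays. BAT1 lost its call without C.NO3 8 hours replicate 3 (adjusted p = 0.0590) and JAL33 without any of 8 arrays (0.0513 to 0.0591), which were C.NO3 2 hours replicate 2, Sp.NO3 2 hours 1, C.NO3 8 hours 3, Sp.KCl 8 hours 2, C.NO3 2 days 1, Sp.NO3 2 days 1 and 3, and Sp.KCl 2 days 1. The count was 7 with the 3′–5′ index as a covariate, 8 without a filter on dim probe sets and 5 without a variance trend. It was 132 in the blocked fit (79 positive and 53 negative), 59 with a replicate block of 3 levels (30 and 29), 96 by the methods' test (53 and 43) and 57 without the arrays of 2 hours (34 and 23), so that the directions were closer to even there.

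**Figure D3:**
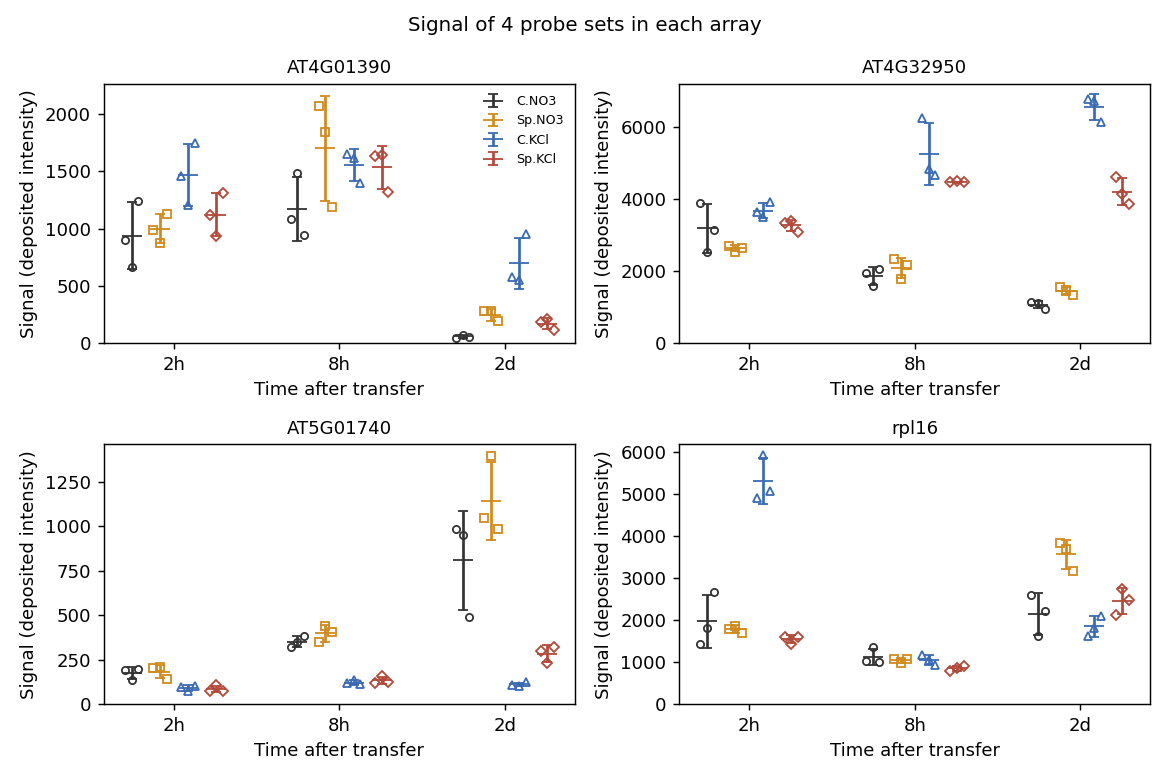
Deposited signal (vertical axis, linear intensity from 0) of AT4G01390, AT4G32950, AT5G01740 and rpl16 in each array, by time after transfer (horizontal axis). Open symbols are single arrays (n = 3 per group), and bars are the group mean ± SD for C.NO3, Sp.NO3, C.KCl and Sp.KCl. The signal of rpl16 in C.KCl at 2 hours, 5311, stood above the 3 other groups of that time.

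More probe sets differed between the times than for any other effect tested, with 12598 of 15922 called. The times may also differ in hour of day and plant age, which the design does not separate from time after transfer. Among the genes of smallest p, the defensin PDF2.1 was higher at 8 hours than at 2 hours by 3.53 and lower at 2 days than at 2 hours by a log2 difference of -1.77 (adjusted p = 1.53e-26). AT1G64370 and AT1G78780 fell by 2 days (-4.28 and -2.97). The DnaJ protein AT1G56300 and the pyruvate decarboxylase PDC2 were higher at 8 hours than at 2 hours, by 2.48 and 2.15. The nitrate response changed with time for 54 probe sets, for 324 in the blocked fit, and for 111 by the methods' test. AT4G32950 differed on nitrate by a further -1.79 at 2 days than at 2 hours (adjusted p = 2.06e-10) and AT5G01740 by a further 1.38 (adjusted p = 0.000804). The effect of the plate changed with time for 1 probe set, that of rpl16 (adjusted p = 1.75e-05), and for 3 in the blocked fit. In rpl16 the C.KCl arrays of 2 hours, which had the high 3′–5′ index, stood apart.

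The probe sets called on uniform plates at 2 hours, 161 higher and 164 lower, were followed as sets between plates at the later times. The higher set was higher on split than on uniform plates in nitrate-fed roots at 2 days, with a mean difference of 0.126 and 119 of 161 members above 0 (adjusted p = 5.82e-10, and p = 0.00425 with an estimated correlation). At 2 days the median difference of that set between nitrate and chloride on uniform plates was 0.00758. Both sets were called against the C.KCl arrays of 2 hours, whose 3′–5′ index averaged 0.755. With the index as a covariate 11 of the 325 were called. Among the nitrate arrays of 2 days the index averaged 0.726 ± 0.112 (SD, n = 3) in C.NO3 and 0.618 ± 0.0406 in Sp.NO3. The higher set was thus higher where the index was lower, at 2 hours and at 2 days. Whether quality carried that result was not tested. The lower set passed at the preset correlation at 8 hours on the nitrate side (mean 0.0598, adjusted p = 0.00608), at 8 hours on the chloride side (-0.0514, adjusted p = 0.00901) and at 2 days on the chloride side (-0.128, adjusted p = 0.000113). So did the higher set on the chloride side at 8 hours (mean -0.0341, adjusted p = 0.0472). With an estimated correlation these lost their calls, at p = 0.345, 0.379, 0.199 and 0.302 in that order. The 3 other sets did not pass: the higher set on the nitrate side at 8 hours (-0.00941), the lower set there at 2 days (-0.0194) and the higher set on the chloride side at 2 days (0.0327). Among 8 tests the higher set at 2 days on the nitrate side held in every fit with an array left out, with means from 0.0741 to 0.179.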

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

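The comparison of same-numbered arrays for the KCl titles and the placing of Sp.KCl 2 days replicate 3 were tests chosen only after the result was seen, as were the splits within same-numbered pairs for the interactions of medium with plate and with time. The fit with the 3′–5′ index as a covariate and the means without the arrays of 2 hours were added after the data were seen.

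The nitrate response differed between uniform and split plates for 18 probe sets by the interaction of medium and plate. The log2 differences between the plates were 1.58 for AT4G01390, 0.74 for rpl16, 1.00 for AT2G28780, 0.54 for BAT1 and -0.52 for JAL33. That of rpl16 rests largely on the C.KCl arrays of 2 hours, which stood apart in its signal and in the 3′–5′ index. Of 100 splits, with plates shuffled within medium and time, 4 gave 18 or more. The highest other split gave 71, several times the real count, which points to a structure of the samples beyond the plates. Of 100 splits that exchange plates only within same-numbered pairs, 1, the real, gave as many (18, highest other 11). In the blocked fit 2 of these gave as many (132, highest other 435), where the 435 again points to a structure of the samples. All of these splits break up any effect of the plate, not the interaction alone. They therefore exclude neither chance for the interaction nor that structure. The count was 70 without Sp.KCl 2 days replicate 3.

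The nitrate response differed between times for 54 probe sets. From 2 hours to 2 days the difference between nitrate and chloride changed by -1.79 for AT4G32950, 1.38 for AT5G01740, 0.99 for rpl16, -0.69 for the EF-hand protein AT2G46600 and -0.62 for AILP1. The blocked count was 324. With salts shuffled within plate and time, 2 of 100 splits gave 54 or more, but the highest other gave 408, which also points to a structure of the samples. With salts exchanged only within same-numbered pairs 4 of 100 gave as many (54, highest other 144), and 2 of 100 in the blocked fit (324, highest other 527). These splits break up any effect of the salt, not its change with time alone. They therefore exclude neither chance for that change nor a structure of the samples. The effect of the plate differed between times for 1 probe set, that of rpl16, whose difference between plates changed by 1.51 from 2 hours to 2 days. Of 100 splits 18 gave 1 or more, with 42 in the highest other, so that chance cannot be excluded for that count. The changes of rpl16 with time, by salt and by plate, both take in the C.KCl arrays of 2 hours.

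The C.KCl arrays of 2 hours stood apart from the other arrays of that time in rpl16 and in the 3′–5′ index, which was higher by 0.375 than in C.NO3. With the index as a covariate, the median ratio of adjusted to unadjusted difference over the 325 probe sets called on uniform plates at 2 hours was 0.771 (quartiles 0.626 and 0.936). The calls fell to 11, where the median size fell from 0.556 to 0.410 and the median SE rose from 0.129 to 0.163, so that smaller differences and lower precision both ended calls. RNA or labelling quality may account for a part of these differences, and index and group cannot be told apart further with 3 arrays per group. A harvest at another hour stays open too, since the difference between C.KCl and C.NO3 correlated with the change from 2 to 8 hours of the split plates at r = 0.196 across probe sets, between the 0.3 set for it and the 0.1 set against it, and the nitrate response itself, the biological difference between these groups, also remains.

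The KCl titles and characteristics contradict each other. If the titles are right and a number marks the same plants, Sp.NO3 and Sp.KCl of a number share plants. Deviations of Sp.NO3 arrays should then resemble those of the same-numbered Sp.KCl more than those of C.KCl. The difference between these correlations averaged 0.141 (SD 0.0932, SE 0.0311) over 9 pairs and was above 0 in 9 of 9 (exact sign-flip test, two-sided, p = 0.00391, the smallest it can give, with pairs of a time not fully independent). By time it was 0.215 at 2 hours, 0.0608 at 8 hours and 0.149 at 2 days. For C.NO3, which would share plants with neither, the same difference averaged 0.000736 (exact p = 0.988), but 0.110 at 2 hours, -0.0699 at 8 hours and -0.0380 at 2 days. A part of the resemblance at 2 hours thus does not need shared plants. Beyond C.NO3 the difference averaged 0.141 (SE 0.0376) and was above 0 in 8 of 9 pairs (exact p = 0.00781). Without 2 hours it was above 0 for Sp.NO3 in 6 of 6 pairs (exact p = 0.0313, again the smallest possible). This argues against exchanged titles if a number marks the same plants on split plates. The titles do not state that. Same-numbered C.NO3 and C.KCl arrays, which share no plants, also correlated above 0.1 in 9 of 9 pairs (mean 0.230).

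At 2 days Sp.KCl replicate 3 lay apart from its group. Each KCl array of that time was placed on 6 axes of its own, drawn from the 5 others, from Sp.KCl (0) to C.KCl (1), so that places of different arrays lie on different axes. Its median place was 0.686 (0.638 to 0.739), with -0.877 (-2.01 to 0.467) and -1.62 (-2.83 to -0.00961) for the other Sp.KCl arrays and 1.52 (1.05 to 1.89), 1.13 (0.658 to 1.54) and 0.652 (0.530 to 0.770) for C.KCl, where the axes of the others include replicate 3. A wrong label may explain the place, but it falls short of the 0.75 set for that. A plant with a weaker response between plates cannot be told apart by place on 3 arrays. In replicate 3 AT4G01390 had a signal of 117, against 191 and 212 in the other Sp.KCl arrays and 556 to 956 in C.KCl. AT4G32950 had 3885, against 4137 and 4618, and 6151 to 6790. AT5G01740 had 319, against 231 and 301, and 104 to 123. For rpl16 it was 2492, against 2122 and 2739, and 1629 to 2114. In AT4G01390, AT4G32950 and AT5G01740 replicate 3 thus lay beyond the other Sp.KCl arrays, away from C.KCl. These genes and rpl16 were named from contrasts that take in replicate 3, which favours a place with its group. They therefore decide neither a wrong label nor a weaker response. The 3′–5′ index of replicate 3, 0.722, was within the 0.519 to 0.821 of the 11 other arrays of 2 days. This was the range set beforehand against RNA or labelling quality. That range spans 4 groups and is too wide to exclude it: the other Sp.KCl arrays had 0.526 and 0.636, and the C.KCl arrays 0.733, 0.782 and 0.519. Quality stays open. Without it the chloride side gave 264 at 2 days against 148.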

How the results depend on the processing

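The fit with the 3′–5′ index as a covariate and the means without the arrays of 2 hours were tests chosen after the data were seen. Where no value below shows it, the cause was not tested. With pseudocount 1 or the filter at the 50th percentile all 21 counts stayed within 1.5 times. Of 164 gene values 91 were called and 73 were not. Of the 91 calls 87 were kept under quantile normalization, 83 with pseudocount 64 and without a variance trend, 79 without a filter, and 91 with a replicate block of 3 or 9 levels. With pseudocount 1 it was 84 of 89, with the filter at the 50th percentile 69 of 69, and with only the arrays compared 61 of 86. The methods' test kept 87 of 91. Exchanged KCl groups kept 53 of 70 calls, with 13 lost and 4 reversed. Of the values not called, calls were gained by 3 and 5 of 73 with 3 and 9 block levels, 5 of 73 with the methods' test and 3 of 53 with exchanged KCl groups, and by 0 in the others. A log2 change of 0.5 on uniform plates at 2 hours was recovered in 29.5% of simulated probe sets, which limits the counts per time. Probe sets whose mean over all arrays corresponds to a signal under about 68.9 were not tested.

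Quantile normalization gave 80 on the chloride side at 2 hours. The sets called on uniform plates at 2 hours were taken anew under each alternative. For these it gave means of -0.0222 for the higher set on the chloride side at 8 hours (call lost) and -0.0329 for the lower on the nitrate side at 2 days (call gained). The filter at the 50th percentile did the same, at -0.0319 and -0.0183. Without a filter the nitrate side at 8 hours gave 1, the chloride side at 2 hours 31 and the interaction of medium and plate 8, and more probe sets were tested. The correlations across probe sets then were 0.222 between plates and -0.0566 between sides. With pseudocount 64 the nitrate side over the times gave 0, and without a variance trend the interaction gave 5.

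Same-numbered arrays were paired in part: over the times 30 of 36 same-numbered pairs of deviations correlated above 0.1 (mean 0.239, from -0.0502 to 0.673). The mean of -0.118 for other numbers adds nothing to this, since the 3 deviations of a group add up to 0. With a replicate block of 3 levels uniform plates gave 926 over the times, 639 at 2 hours, 130 at 8 hours and 650 at 2 days, split plates 70 at 8 hours and 206 at 2 days. The chloride side gave 121 over the times, 116 at 2 hours and 240 at 2 days, and the interactions of medium with plate 59 and with time 143. With the replicate block within time, 9 levels, uniform plates gave 1371, 1176, 296 and 887 and split plates 372, 42, 117 and 305 in the same order. The nitrate side gave 4 over the times and 21 at 8 hours, the chloride side 272, 308 at 2 hours and 404 at 2 days, medium with plate 132, medium with time 324 and plate with time 3. Set means with 3 levels were -0.0230 (higher, chloride side, 8 hours, lost) and -0.0347 (lower, nitrate side, 2 days, gained). With 9 levels they were -0.0159 and -0.0312, with -0.0282 (lower, chloride side, 8 hours, lost) and 0.0351 (higher, chloride side, 2 days, gained).

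With exchanged KCl groups uniform plates gave 135 over the times, 26 at 2 hours and 61 at 2 days, and split plates 462, 150 and 398. The chloride side gave 39, 53 and 148 with the directions reversed, which follows from the exchange, so that its single genes are not listed. Medium with plate gave 0 and plate with time 8. The higher set, here 26 probe sets, had a mean of 0.141 on the nitrate side at 8 hours (call gained), where -0.00941 had not been called. That contrast uses no KCl arrays, so only the set changed. On the chloride side at 8 hours, where the exchange itself turns the sign, the mean was 0.0692. The correlations were 0.460 between plates and 0.120 between sides, the latter reversed, which also follows from the exchange. rpl16 reversed to 0.31 on uniform plates at 2 hours, and in the interaction rpl16 (-0.37), AT2G28780 (-0.28) and JAL33 (0.27) reversed without a call.

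With only the arrays compared, and so fewer degrees of freedom, uniform plates gave 8 and split plates 0 at 2 hours. The nitrate side gave 0 over the times and 1 at 8 hours, and the chloride side 12, 1 at 2 hours and 91 at 2 days. The higher set, here 6 probe sets, had means of 0.129 (nitrate side, 8 hours, call gained) and -0.00679 (chloride side, 8 hours, lost). The methods' test gave 873 on uniform plates over the times and 125 at 8 hours, and 389, 40 and 86 on split plates over the times and at 2 and 8 hours. The nitrate side gave 120, 4, 36 and 19 and the chloride side 423, 160 and 5 at 2 and 8 hours, with 96 for medium with plate and 111 for medium with time. It takes a p below 0.05 for a comparison within the 6084 probe sets that passed its model test, without an adjustment across them. The index as a covariate gave 11 on uniform plates at 2 hours, 10 over the times and 6 at 2 hours on the chloride side, and 7 for medium with plate. Without the arrays of 2 hours the nitrate side gave 3 and medium with plate 57.

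With each array left out in turn, uniform plates gave 364 to 748 over the times, 53 to 711 at 2 hours, 33 to 66 at 8 hours and 245 to 317 at 2 days. Split plates gave 153 to 198, 12 to 16, 29 to 37 and 77 to 128, the nitrate side 0 to 1, 0 to 0, 0 to 0 and 1 to 1, and the chloride side 9 to 235, 11 to 119, 0 to 0 and 52 to 264. Medium with plate gave 6 to 70, medium with time 42 to 75, plate with time 1 to 2, time 12393 to 12597 and the list calls 8 to 12. The correlations were 0.275 to 0.413 and -0.182 to -0.0666. Means of the higher and lower set were -0.0308 to 0.0683 and 0.0322 to 0.110 on the nitrate side at 8 hours, 0.0741 to 0.179 and -0.0472 to 0.0319 there at 2 days, -0.0749 to 0.0208 and -0.0998 to -0.00139 on the chloride side at 8 hours, and 0.00455 to 0.0923 and -0.259 to -0.0419 there at 2 days. Chloride-side counts were highest without Sp.KCl 2 days replicate 3 over the times and at 2 days, and at 2 hours without Sp.KCl replicate 1. Where a group was left with 2 arrays, it was assumed to vary like the other groups. Of 1176 named-gene values that were called as reported 991 kept their call and 185 lost it, and 0 of 1314 that were not called gained one.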

Other observations

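The tests of gene families and of plastid-encoded genes were chosen only after the data were seen. The tests on other splits were planned.

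On split plates 51 of 59 tested plastid-encoded genes had a higher signal on the nitrate side over the times (median log2 0.14, adjusted p = 7.87e-07, but adjusted p = 0.772 with an estimated correlation). In nitrate-fed roots 45 of 59 had a higher signal on split than on uniform plates (median 0.06, adjusted p = 0.00281, and adjusted p = 0.808 with an estimated correlation). In chloride-fed roots 12 of 59 did (median -0.18, adjusted p = 1.06e-05, and adjusted p = 0.586 with an estimated correlation), 13 of 59 at 2 hours (median -0.26, adjusted p = 2.81e-06, and 0.668) and 8 of 59 at 8 hours (median -0.26, adjusted p = 1.97e-11, and 0.636). On uniform plates at 2 hours 10 of 59 were higher on nitrate, 5 were called lower, and the median was -0.31 (adjusted p = 3.75e-06, and adjusted p = 0.683 with an estimated correlation). The C.KCl arrays of 2 hours had the highest mean 3′–5′ index of that time, 0.755.

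Among gene families, 6 of 7 expansins of the A class, wall-loosening proteins, had a higher signal on nitrate on uniform plates at 2 hours (median 0.26, adjusted p = 0.0224), and the set did not pass with an estimated correlation. Of 10 glycosyl hydrolases of family 9, 1 had a higher signal there (median -0.26, adjusted p = 0.0272, and adjusted p = 0.224 with an estimated correlation). Both rest on the C.KCl arrays of 2 hours, with an index of 0.755 against 0.381 in C.NO3. Of 11 autophagy proteins, 1 had a higher signal on the nitrate side of split plates over the times (median -0.11, adjusted p = 0.00445, and adjusted p = 0.772 with an estimated correlation). On nitrate 2 of 11 were higher on split than on uniform plates (median -0.08, adjusted p = 0.00281, and 0.808), and on uniform plates at 2 days 1 of 11 was higher on nitrate (median -0.16, adjusted p = 0.0261, and 0.725). These were the sets past 0.05 among 17 families or groups of genes tested in 10 comparisons each, and the adjustment was made within a comparison. With an estimated correlation no set had an adjusted p below 0.05. Under quantile normalization the median of each of these sets kept its sign in the comparisons given here.

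Other splits of the arrays were tested for each count. Over the times, each with 100 splits that shuffled salts or plates within time, the real split of nitrate against chloride was the only 1 to reach its count on uniform plates (541, highest other 211) and on split plates (186, highest other 9). So was that of the chloride side (39, highest other 19) and, with times shuffled within salt and plate, that of time (12598, highest other 423). Chance can be excluded for the counts of uniform plates and of time under such splits, which ignore the repeat number. Among 100 splits that part every same-numbered pair on uniform plates, the real split was also the only 1 (highest other 309). Splits of that kind were not run for split plates and the chloride side, where 8 and 6 of 9 same-numbered pairs correlated above 0.1. For the counts of split plates and the chloride side chance is therefore not excluded. Without Sp.KCl 8 hours replicate 2 the chloride side gave 9. With labels shuffled within time, 5 of 100 splits gave as many as the real 1 on the nitrate side (highest other 1). As many as the 10 list calls came from 7 of 100 (highest other 17), so that chance cannot be excluded for these.

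At a single time 6 arrays make 10 splits, too few for a share under 0.05. On uniform plates 1 split, the real, gave as many at 2 hours (325, highest other 8), at 8 hours (62, highest other 0) and at 2 days (402, highest other 1). On split plates 2 gave as many at 2 hours and 1 at 8 hours (39, highest other 0) and at 2 days (127, highest other 1). The other at 2 hours called 1301 against the real 23. It set Sp.NO3 replicates 1 and 2 and Sp.KCl replicate 1 against the rest, which keeps the arrays numbered 1 together and those numbered 3, and points to a structure by repeat number. The 3 other splits that part every pair gave 0, and the blocked count was 42. On the nitrate side 10, 10 and 3 splits gave as many as the real 0, 0 and 1 (highest other 28, 1 and 5). On the chloride side 1, 10 and 1 gave as many as the real 53, 0 and 148 (highest other 0, 2 and 11). The 11 came from C.KCl replicates 1 and 2 with Sp.KCl replicate 3.

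For the sets of probe sets called at 2 hours, 10 splits are likewise too few. On the nitrate side at 8 hours 7 splits gave a mean as far from 0 for the higher set (-0.00941, highest other 0.0364) and 2 for the lower (0.0598, highest other 0.0766). At 2 days there 1 did for the higher (0.126, highest other 0.0732) and 3 for the lower (-0.0194, highest other 0.0279). On the chloride side at 8 hours 7 did for the higher (-0.0341, highest other 0.0887) and 5 for the lower (-0.0514, highest other 0.0876), and at 2 days 4 for the higher (0.0327, highest other 0.0762) and 3 for the lower (-0.128, highest other 0.173).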
